A study of Oncorhynchus mykiss with 15 samples.

How the data were processed

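Gene expression was measured by RNA sequencing in mature adipocytes of adult rainbow trout (Oncorhynchus mykiss). Per the labels, the fish were held at 15 °C without any treatment and were fasted for 24 h before sampling. Fat was dissected from 3 depots, and the adipocytes were released mechanically and with collagenase type II. Total RNA was taken up in TRIzol, ribosomal RNA was removed, and libraries were read as pairs of 150 bp on a NovaSeq instrument. A separate set of small RNA libraries mentioned in the labels was not analysed here.

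The values used were the raw counts per gene deposited by the authors, in a table of 64494 genes and 15 libraries. Per the submitters' processing notes, the tools were Trimmomatic 0.30, which trims reads, STAR 2.5.2b, which aligns them, featureCounts from Subread 1.5.2, which counts them per gene, and DESeq2 1.6.3, which normalizes and tests counts. The genome build, the annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here. The salmonid genome holds many pairs of similar gene copies. A count for a gene with a near-identical copy is therefore uncertain, as is a count for a gene that overlaps another. Tests on the table found whole numbers in every column, library totals that differ, and 0 lines without a gene identifier.

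The table gives Ensembl gene identifiers and does not pair them with names, and the supplied gene table carried an Ensembl identifier in 0 of its lines. No gene is therefore named. The 33 gene lists fixed before the data were examined, which covered adipocyte functions and markers of other cell types, could not be matched to identifiers. Their tests, the shares of counts in markers of other cell types, and the fits without the genes of those markers were not run, so the purity of the adipocytes was not assessed. The naming rule, also fixed before the data were examined, took for each comparison the 10 genes with the largest log2 fold change in each direction. They had to pass the test, average at least 10 CPM (counts scaled to a common library total) in the higher depot, and separate all 5 libraries of that depot from all 5 of the other. Of these, the identifiers of the first 2 in each direction are printed. ENSOMYG00000055678, the gene with the most counts, was added after its values had been seen.

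Groups were taken from the sample titles, with 5 libraries for each depot. The labels do not say which fish gave which library. The p-values therefore measure the spread between these libraries, some of which may share a fish. A chi-square comparison of all 30 pairs of libraries within depots gave at least 6.37 per degree of freedom, so no pair agreed within counting noise and each library counted once. No sequencing batch is given in the labels.

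Differences between depots were tested with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, with TMM normalization and robust estimates of dispersion, in a single fit of all 15 libraries with depot as the only term. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15. This left 25695 genes, which held 99.0% of all counts. Another 12838 genes had no counts in any library. TMM factors ran from 0.501 to 1.29. P-values were adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. The SE printed with an edgeR log2 fold change is the size of that change divided by the square root of its F statistic. It was not estimated separately and is only a rough guide, above all for genes with few counts in a depot. A gene was taken as higher in a depot than in both others when both comparisons passed that threshold with a log2 fold change above 1. Single measures per library were compared by exact two-sided permutation tests, 5 against 5, with 252 arrangements and a smallest possible p of 0.00794. These p-values were adjusted over 18 tests. Principal components and correlations used log2 CPM with a prior count of 2. Detected genes had at least 1 count, and they were counted again after each library had been thinned at random to 2413951 counts.

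The tests were run on simulated counts with known changes, drawn with the spread of each gene in a fit of the real counts. In the simulation of IMAT against VAT, over 25015 genes, 53.1% of the genes changed 4-fold and 5.05% of those changed 2-fold were recovered. The recovery was 42.9% and 4.04% for IMAT against SAT over 25015 genes, and 59.1% and 9.38% for VAT against SAT over 24986 genes. Most 2-fold differences in these simulated counts thus went undetected. Few genes were changed, with 99 tested genes at 2-fold and 98 at 4-fold for IMAT against VAT, where 57 were called. The Benjamini-Hochberg threshold is stricter where fewer genes differ. Recovery in the real comparisons may therefore be higher and was not measured. Confidence intervals of 95% on shares (Clopper-Pearson) and on ratios of counts (exact Poisson) cover counting error only, as does the floor of 3 counts set for a depot with none.

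Alternatives fixed before the data were examined were RLE and upper-quartile factors, no filter, a filter of 1 CPM in 5 libraries, DESeq2 1.42.0, limma-voom from limma 3.58.1, fits of only the 2 depots compared, the replicate number as a block, glmTreat against a log2 fold change of 1, and each library left out in turn. Thinning to equal depth, leaving out the gene with the most counts, and leaving out 3 libraries with more detected genes were added after the data had been seen.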

Results

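Mature adipocytes of rainbow trout were compared between visceral fat (VAT), which lies around the internal organs, subcutaneous fat (SAT), which lies beneath the skin, and intramuscular fat (IMAT), which lies within the muscle. The series was set up as a comparison of these 3 depots under ordinary rearing conditions. Each depot was represented by 5 libraries. Total counts per library averaged 7981785 ± 1445536 (SD, n = 5) in VAT, 5822760 ± 1129726 in SAT and 2825769 ± 774457 in IMAT. All 5 IMAT totals lay below all totals of VAT and of SAT (exact two-sided permutation test, p = 0.00794 for each, the smallest the design can give, and 0.0238 after adjustment over 18 tests). A floor of 3 counts corresponded to 0.319 to 0.511 CPM in the VAT libraries and to 0.714 to 1.24 CPM in the IMAT libraries, so low transcripts were measured least precisely in IMAT.

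Fewer genes were detected in the IMAT libraries, which were also the shallowest. A mean of 32025 ± 3104 genes (SD, n = 5) had at least 1 count in IMAT, against 39816 ± 2435 in VAT and 41430 ± 3987 in SAT, and both differences from IMAT passed the test (exact permutation, p = 0.00794, adjusted p = 0.0238 over 18 tests). At equal depth the means were 31623 ± 3579, 33668 ± 2086 and 36913 ± 4625, and no pair of depots passed (exact permutation, adjusted p = 0.349 for IMAT against VAT, 0.132 for IMAT against SAT and 0.265 for VAT against SAT). The 10 most abundant genes took 21.5% ± 14.4 of the counts in IMAT (SD, n = 5), 9.36% ± 1.44 in VAT and 10.4% ± 1.31 in SAT, a difference that passed against VAT (exact permutation, adjusted p = 0.0238) and not against SAT (adjusted p = 0.0536). ENSOMYG00000055678 had the most counts in each of the 15 libraries. It took 11.2% ± 11.7 of the counts in IMAT (SD, n = 5), 2.68% ± 0.789 in SAT and 1.92% ± 0.253 in VAT. This share passed the exact permutation test for IMAT against VAT (adjusted p = 0.0238) and did not for IMAT against SAT (adjusted p = 0.0536) or VAT against SAT (adjusted p = 0.0779). Its share in IMAT replicate 2 was 31.5% (95% Clopper-Pearson interval 31.4 to 31.5%), and the other 4 IMAT libraries lay between 3.47% and 10.8%. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment its normalized count was higher in IMAT than in VAT (log2 fold change 3.31, SE 0.705, adjusted p = 0.00183) and than in SAT (2.82, SE 0.69, adjusted p = 0.0113). IMAT replicate 2 decided much of the size, since without it the log2 fold change was 1.81 against VAT and 1.32 against SAT (adjusted p = 0.00265 and 0.045 by the same edgeR test and adjustment). The difference from SAT did not pass with the replicate number as a block (log2 fold change 2.00, adjusted p = 0.0608 by the same edgeR test and adjustment) or in the edgeR test against a log2 fold change of 1 (Benjamini-Hochberg adjusted p = 0.0569). The log2 fold change against VAT was 2.56 with the block, and limma-voom gave 2.37 against VAT and 1.89 against SAT. Its log2 fold change in VAT against SAT was -0.49 (SE 0.646, adjusted p = 0.775 by the same edgeR test and adjustment).

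The 3 depots separated along the first principal component, which held 43.9% of the variance, with SAT between VAT and IMAT. The mean score was -107.9 ± 6.33 in VAT (SD, n = 5), -19.3 ± 2.94 in SAT and 127.1 ± 48.8 in IMAT. Correlations of log2 CPM across genes averaged 0.913 between VAT libraries, 0.914 between SAT libraries and 0.823 between IMAT libraries. Between depots they averaged 0.843 for VAT and SAT, 0.767 for IMAT and SAT and 0.657 for IMAT and VAT. Without IMAT replicate 2 the means were 0.854 between IMAT libraries, 0.795 for IMAT and SAT and 0.685 for IMAT and VAT. The IMAT libraries also had the fewest counts, and how far counting noise lowered their correlations was not tested. Genes are not independent replicates, so these values describe the libraries only.

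**Figure D1:**
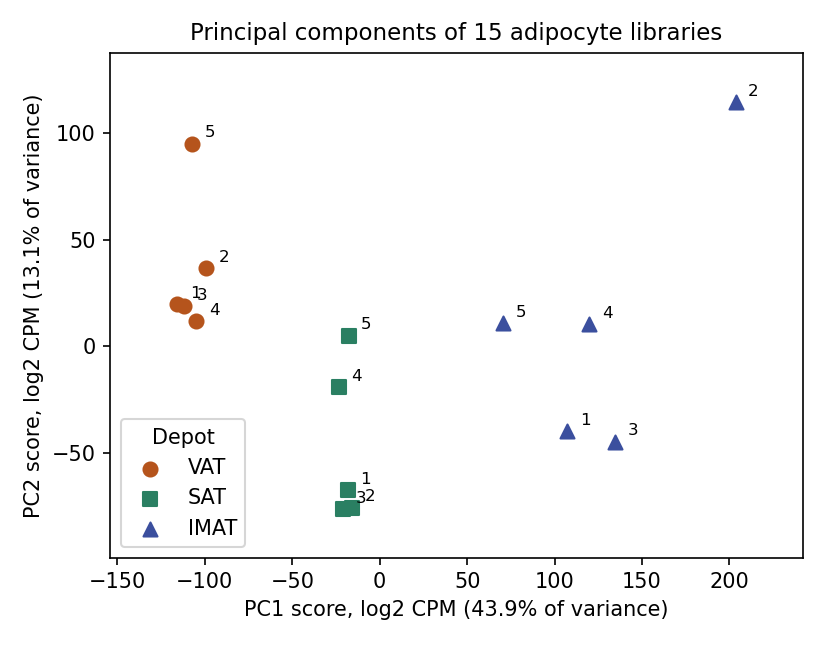
Scores of the 15 libraries on the first and second principal components of log2 CPM, with 1 point per library, coloured by depot and numbered by replicate. VAT libraries lie between -115.7 and -99.3 on the horizontal axis, SAT libraries between -23.2 and -15.8, and IMAT libraries between 70.6 and 203.5, where IMAT replicate 2 stands farthest out.

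Among the adipocyte preparations, whose purity was not assessed, those of intramuscular and visceral fat differed most. Of 25695 genes tested, 3355 were higher and 2087 were lower in IMAT than in VAT. ENSOMYG00000020573 averaged 251.3 ± 58.4 CPM (SD, n = 5) in IMAT and had 2 counts in all VAT libraries together. ENSOMYG00000045128 averaged 1913 ± 1404 CPM in IMAT and 0.481 ± 0.491 CPM in VAT. In the other direction, ENSOMYG00000002109 averaged 190.3 ± 183.3 CPM in VAT and had 0 counts in the 5 IMAT libraries, and ENSOMYG00000025354 averaged 355.5 ± 347.2 CPM in VAT and had 1 count in IMAT.

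The pooled ratio of IMAT to VAT was 5244 for ENSOMYG00000020573 (95% counting interval 1450 to 43300) and 3688 for ENSOMYG00000045128 (2390 to 6040). ENSOMYG00000002109 was at least 792.1-fold lower in IMAT, with the floor of 3 counts set over the depot, and the pooled ratio of VAT to IMAT was 4397 for ENSOMYG00000025354 (789 to 174000). Without VAT replicate 2 the bound for ENSOMYG00000002109 was 515.3 and the ratio for ENSOMYG00000025354 was 2852, and the latter became a bound of 1215 without IMAT replicate 3, which held its only IMAT count. The ratio for ENSOMYG00000020573 was 8056 without VAT replicate 3, 8014 without VAT replicate 5 and at its lowest 4213 without VAT replicate 1. That for ENSOMYG00000045128 ran from 2686 without IMAT replicate 4 to 5123 without VAT replicate 5. These ratios with libraries left out were added after the data had been seen. Adjusted p-values of edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment were 1.24e-09, 4.09e-09, 2.48e-06 and 6.19e-08 in the order named. By fitted fold change, 642 of the genes higher in IMAT and 92 of those lower differed over 32-fold. Among 1490 genes with at least 100 CPM on average over all libraries, 281 were higher and 317 were lower in IMAT. The 5 libraries of the depots did not overlap in 15.0% of the genes tested, against 0.794% by chance. The total of 5442 genes fell to 2581 under a test against a log2 fold change of 1. The 2087 genes lower in IMAT were 1269 in a fit of only these 2 depots, 1384 at equal depth, an alternative chosen after the data were seen, and 520 under the test against a log2 fold change of 1, where the 3355 higher were 2061.

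Intramuscular and subcutaneous adipocyte preparations differed in 2716 genes, with 1889 higher and 827 lower in IMAT. ENSOMYG00000018097 averaged 460.3 ± 191.4 CPM (SD, n = 5) in IMAT and 0.617 ± 0.28 CPM in SAT. ENSOMYG00000070655 averaged 2570 ± 710.0 CPM in IMAT and 5.12 ± 1.61 CPM in SAT. The genes lower in IMAT by the largest fold had lower levels in SAT than the genes above had in IMAT. ENSOMYG00000034080 averaged 19.6 ± 7.55 CPM in SAT and 0.555 ± 0.596 CPM in IMAT. ENSOMYG00000016098 averaged 12.3 ± 6.65 CPM in SAT and 0.382 ± 0.385 CPM in IMAT. The VAT libraries had 44.8 to 192.2 CPM of ENSOMYG00000034080, which was thus highest in VAT, and 0.531 to 4.43 CPM of ENSOMYG00000016098.

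By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the log2 fold change was 9.96 for ENSOMYG00000018097 (SE 0.728, adjusted p = 6.05e-08) and 9.41 for ENSOMYG00000070655 (SE 0.732, adjusted p = 9.69e-08). By the same edgeR test and adjustment it was -4.96 for ENSOMYG00000034080 (SE 0.64, adjusted p = 2.51e-05) and -4.54 for ENSOMYG00000016098 (SE 0.761, adjusted p = 0.000431), and the latter was -5.26 without IMAT replicate 2. Fitted differences over 32-fold were found in 204 of the genes higher in IMAT and in 6 of those lower. Of the 1490 abundant genes, 164 were higher and 191 were lower in IMAT. The libraries did not overlap in 9.19% of the genes tested, against 0.794% by chance. The count of 2716 genes was 4143 with DESeq2, 4351 without VAT replicate 5 and SAT replicates 4 and 5, an alternative chosen after the data were seen, and 1079 in a test against a log2 fold change of 1. The count of 827 genes lower in IMAT depended on single libraries, with 402 without SAT replicate 2, 429 without SAT replicate 3, 492 without SAT replicate 1, 535 without IMAT replicate 4 and 1279 without VAT replicate 5. It was 1492 with DESeq2, 1963 without the 3 libraries together and 71 in the test against a log2 fold change of 1, where the 1889 higher were 1008.

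Visceral and subcutaneous adipocyte preparations differed in 2090 genes, and most of these were lower in VAT, with 609 higher and 1481 lower. ENSOMYG00000076661 averaged 363.6 ± 517.2 CPM (SD, n = 5) in VAT and 1.51 ± 1.44 CPM in SAT, and ENSOMYG00000012696 averaged 1194 ± 1106 CPM in VAT and 5.92 ± 3.45 CPM in SAT. ENSOMYG00000020373 averaged 385.3 ± 86.1 CPM in SAT and 1.88 ± 1.46 CPM in VAT, and ENSOMYG00000075984 averaged 104.6 ± 65.5 CPM in SAT and 0.55 ± 0.296 CPM in VAT. The IMAT libraries had 237.6 to 372.1 CPM of ENSOMYG00000020373 and 35.7 to 189.3 CPM of ENSOMYG00000075984, so both genes were low in VAT alone.

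The log2 fold change in VAT against SAT was 7.99 for ENSOMYG00000076661 (SE 0.922, adjusted p = 1.1e-05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment) and 7.68 for ENSOMYG00000012696 (SE 0.824, adjusted p = 5.12e-06). It was -7.70 for ENSOMYG00000020373 (SE 0.533, adjusted p = 7.37e-08 by the same edgeR test and adjustment) and -7.52 for ENSOMYG00000075984 (SE 0.751, adjusted p = 2.43e-06). The high SD of the genes higher in VAT came with a wide range between VAT libraries, from 44.5 CPM in replicate 5 to 1281 CPM in replicate 2 for ENSOMYG00000076661. Without VAT replicate 2 the log2 fold change was 6.56 for ENSOMYG00000076661 and 6.99 for ENSOMYG00000012696. At equal depth it was -6.35 for ENSOMYG00000075984, with the replicate number as a block it was 7.17 for ENSOMYG00000076661, and without VAT replicate 5 and SAT replicates 4 and 5 it was 9.07 for ENSOMYG00000076661. Of the 1490 abundant genes, 69 were higher and 177 were lower in VAT. The libraries did not overlap in 8.66% of the genes tested, against 0.794% by chance. The count of 2090 genes fell to 1387 when all libraries were thinned to equal depth, an alternative chosen after the data were seen, and to 896 in a test against a log2 fold change of 1. The 1481 genes lower in VAT were 977 and 671 under these alternatives, and the 609 higher were 225 under the latter.

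**Figure D2:**
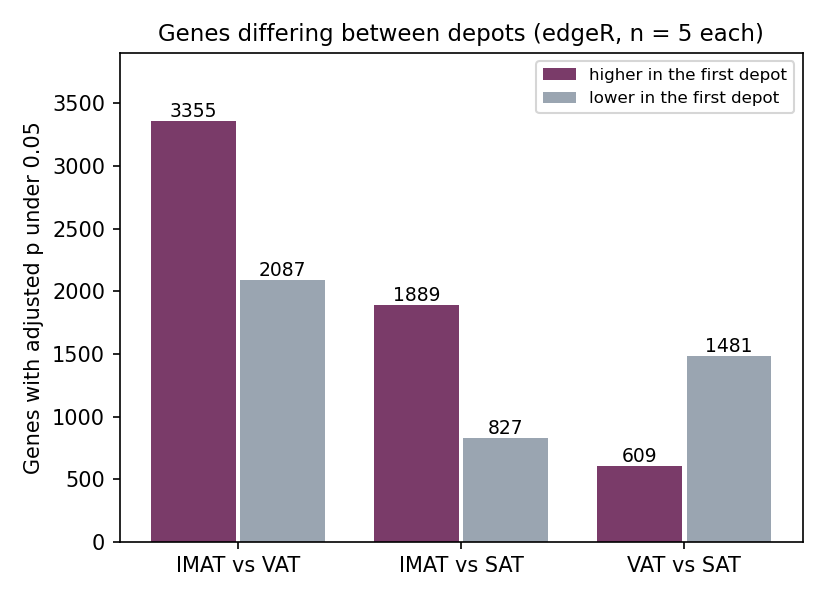
Number of genes with an adjusted p under 0.05 in edgeR's quasi-likelihood test, for each pair of depots with 5 libraries each. Dark bars count genes higher in the depot named first and pale bars count genes lower in it, from 3355 and 2087 for IMAT against VAT to 609 and 1481 for VAT against SAT.

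**Figure D3:**
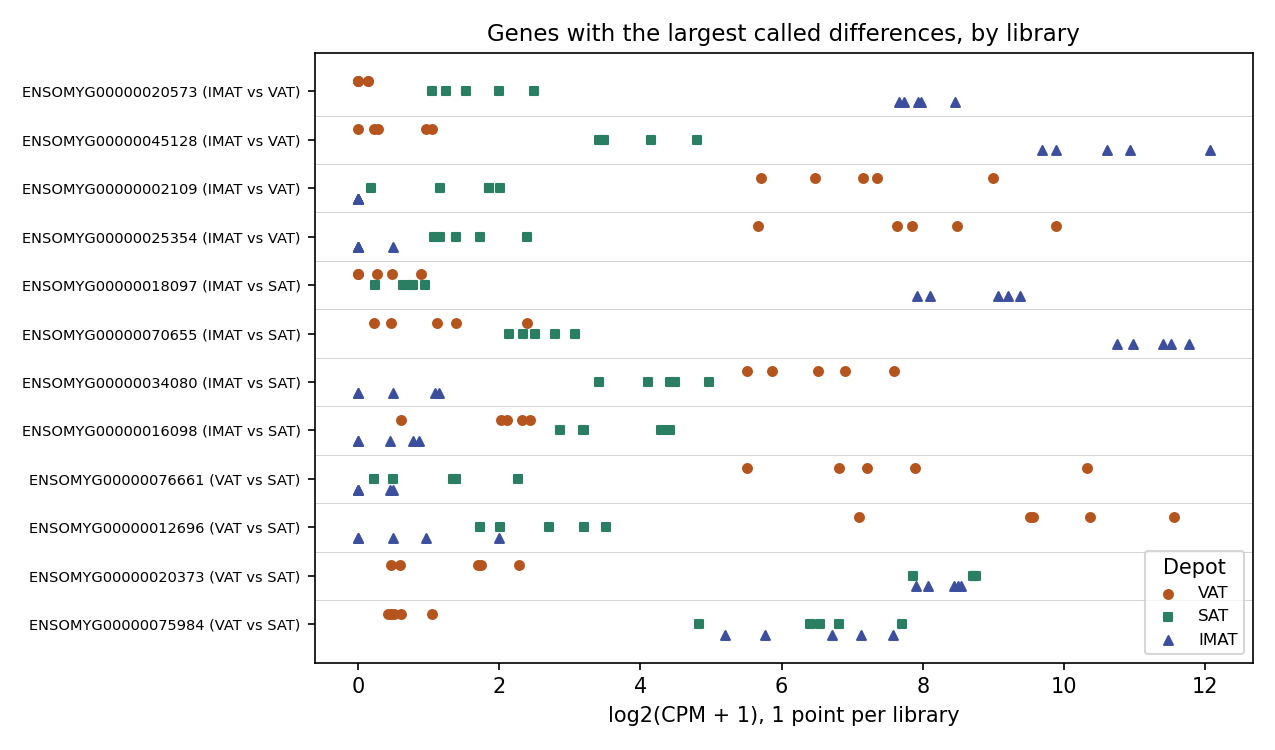
Expression of the 12 genes printed for the 3 comparisons, as log2 of CPM plus 1, with 1 point per library and the comparison that selected each gene in parentheses. In the comparison that selected it, all 5 libraries of the higher depot lie to the right of all 5 of the lower depot, as the rule of selection required.

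A joint test of all 3 depots found 5278 differing genes, 20.5% of those tested. For most genes that differed between IMAT and VAT, the mean in SAT lay between them. This held for 2718 of the 3355 genes higher in IMAT (81.0%) and for 1792 of the 2087 genes lower in IMAT (85.9%). Positions were taken from the fitted log2 fold changes, with VAT at 0 and IMAT at 1. On this log2 scale the median position of SAT was 0.405 for the genes higher in IMAT and 0.409 for the genes lower in IMAT. Of the 3355 genes higher in IMAT than in VAT, 1197 were also higher in SAT than in VAT and 1664 were also higher in IMAT than in SAT. Of the 2087 genes lower in IMAT, 438 were also lower in SAT than in VAT and 510 were also lower in IMAT than in SAT. These genes were chosen by their difference between the end depots, which by itself favours a middle position for SAT.

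The number of genes that stood above both other depots was largest in IMAT and smallest in SAT. There were 1568 such genes in IMAT, 412 in VAT and 96 in SAT, and the fitted difference from both other depots exceeded 32-fold for 200, 43 and 0 of them. The 1568 genes took 33.6% ± 18.2 of the counts in IMAT (SD, n = 5), 4.67% ± 0.813 in SAT and 3.05% ± 0.371 in VAT. The 412 genes took 6.61% ± 1.80 of the counts in VAT, 1.19% ± 0.0247 in SAT and 0.622% ± 0.218 in IMAT. The 96 genes took 1.06% ± 0.190 of the counts in SAT, 0.323% ± 0.0492 in VAT and 0.316% ± 0.129 in IMAT. The genes were chosen on these libraries, so their shares were not tested. All but 8 of the 1568 genes had counts in VAT, and all but 8 of the 412 had counts in IMAT.

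Both comparisons behind each of these counts use the same libraries of the depot. In 10 simulated data sets without differences, 0 genes stood above both other depots. Such data hold no differing genes, so they do not measure how shared libraries raise the overlap among genes that differ. Lists of the same lengths drawn independently would share 213 genes for IMAT, 35.3 for VAT and 38 for SAT. When the libraries of the depot were divided so that the comparisons shared none, the median overlap over 20 divisions was 1165 genes (796 to 1425) for IMAT, 283 (242 to 340) for VAT and 28.5 (14 to 49) for SAT, where independent lists would share 162, 29.4 and 10.1. Single libraries decided part of the count for SAT, which was 63 without SAT replicate 1, 38 without SAT replicate 2 and 48 without SAT replicate 3. It was also 173 with DESeq2 and 226 without VAT replicate 5 and SAT replicates 4 and 5.

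**Figure D4:**
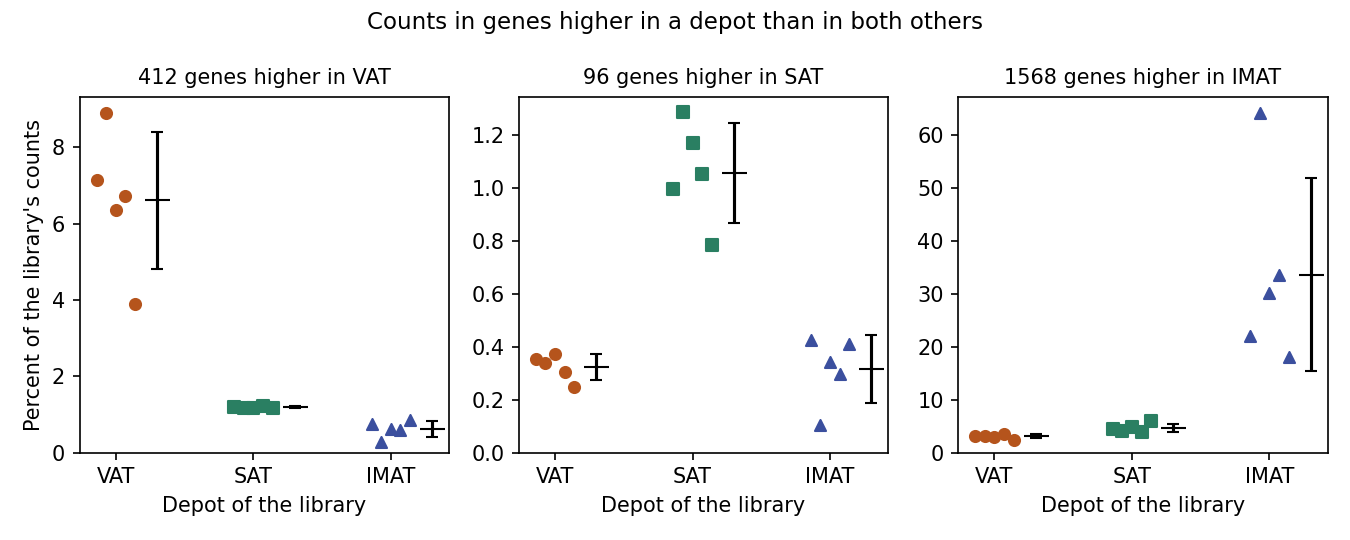
Percent of each library's counts in the 412, 96 and 1568 genes higher in VAT, SAT and IMAT than in both other depots, with 1 point per library, a horizontal mark for the mean and bars for the SD (n = 5). Each panel has its own vertical axis, and the highest single value is 64.1% for IMAT replicate 2.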

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

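The tests for the 3 libraries with more detected genes, described last, were chosen after the detected genes had been seen, and the leak of reads was tested on all genes of each set only after the result on the more abundant ones. Among 39 groups of 5 libraries examined, 6 held a library whose gap to the nearest other exceeded 0.71 of the whole range. For independent groups of normally distributed values, chance alone would give about 1.95. The groups were unlogged counts, shares and CPM, and some are linked measures of the same libraries, so that figure is only a rough guide. IMAT replicate 2 stood apart by its total of 4199494 counts (2413951 to 2655266 in the other IMAT libraries), by the 31.5% of its counts in ENSOMYG00000055678 (3.47 to 10.8%) and by the 61.4% in its 100 most abundant genes (25.4 to 35.7%). VAT replicate 2 stood above the other VAT libraries with 508.8 CPM of ENSOMYG00000002109 (51.2 to 162.2 CPM) and 1281 CPM of ENSOMYG00000076661 (44.5 to 235.2 CPM). SAT replicate 5 stood below the other SAT libraries with 231.4 CPM of ENSOMYG00000020373 (417.8 to 430.9 CPM).

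The genes over 32-fold higher in a depot than in both others, 43 in VAT and 200 in IMAT, varied together between the libraries of that depot. The 43 genes lay from -1.85 (VAT replicate 5) to 1.6 (VAT replicate 2) around their mean on the log2 scale, and the 200 genes from -0.91 (IMAT replicate 5) to 1.34 (IMAT replicate 2). A second source of RNA present in varying amounts may account for this, since a single factor per library held 94.2% of the variance of the VAT genes and 84.1% of that of the IMAT genes, above the 95th percentile of 87.1% and 56.0% in 1000 random sets of matched level. Coordinated regulation in the adipocytes of a depot would give the same pattern and stays open, and without gene names no source could be tested by its markers. Reads leaking at a fixed ratio to the pooled counts of the source depot do not account for all the low counts elsewhere. The SD over genes of the log2 ratio to that depot was at least 0.679 for the 39 VAT genes and 0.989 for the 132 IMAT genes with at least 1000 counts in it. For all 43 and 200 genes it was at least 0.715 and 0.966. Counting noise at a fixed ratio reached 0.343 and 0.176 (0.484 and 0.443 for all genes) in the same receiving depot, SAT. A leak of unequal size from the source libraries was not simulated and stays open.

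In IMAT replicate 2, the 31.5% of counts in ENSOMYG00000055678 was not the only departure. With that gene left out and the normalization repeated, the library still deviated from the other IMAT libraries by a median of 0.802 on the log2 scale, against at most 0.53 for any of the other 4, which argues against this gene alone setting the library apart. The gene exceeded its mean in the other IMAT libraries by 3.49 on the log2 scale. This lies at percentile 99.8 of the other genes higher in IMAT than in both other depots. It also lies outside their central 95% of -1.24 to 2.78, the bound set against a rise in step with them. The bounds for this library were set before these results but after the gene's share had been seen. As the gene was singled out by its share in this same library, an extreme value was built into that test, and whether it rose in step was not decided. A difference between fish, a difference in the isolation and reads shared between gene copies stay open, and no biological explanation was tested, as the design gives none within a depot.

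More genes were detected in VAT replicate 5 (43239), SAT replicate 4 (46175) and SAT replicate 5 (44738) than in the other libraries of their depots. Depth may account for the excess of VAT replicate 5 over VAT replicate 2 (35495 genes at equal depth against 36338), but not over VAT replicates 1, 3 and 4, which had 31812 to 32356, and SAT replicates 4 and 5 still had 41509 and 41901 against at most 35983 in SAT replicates 1 to 3. Low background reads spread over all genes would alone leave abundant genes, of at least 100 CPM, in place. Yet 114 such genes exceeded the other libraries over 2-fold in VAT replicate 5 (at most 37 in VAT replicates 1 to 4). In SAT replicate 5, 37 did (at most 13 in SAT replicates 1 to 3), while the 17 in SAT replicate 4 lay too close to 13 to decide. These rises argue against background as the only difference of VAT replicate 5 and SAT replicate 5. They cannot exclude it as the source of the extra detected genes, since both can occur together. IMAT replicate 2 had 186 such genes and the fewest detected genes of its depot at equal depth (27185). A fish or day shared by libraries of the same number stays open for number 5, where IMAT replicate 5 had the most genes of its depot at equal depth (35937 against at most 34496), and for number 4, where IMAT replicate 4 ranked second in its depot (34496) but VAT replicate 4 had the fewest genes of its depot (31812). No biological explanation was tested.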

How the results depend on the processing

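Thinning to equal depth, leaving out ENSOMYG00000055678 and leaving out VAT replicate 5 with SAT replicates 4 and 5 were chosen after the data had been seen. RLE and upper-quartile factors, both other filters, limma-voom, fits of only the 2 depots compared and the fit without ENSOMYG00000055678 moved none of the counts of differing genes, or of genes above both other depots, by over 1.5 times. The genes lower in IMAT than in VAT, 2087 in all, were 1269 in the fit of 2 depots. With DESeq2, 4143 genes differed between IMAT and SAT and 173 were higher in SAT than in both other depots, and the cause was not tested. The median log2 fold change over the genes of each fit in VAT against SAT was -0.25 with DESeq2 and 0.03 with edgeR after its filter. With edgeR and no filter on low counts it was -0.16. This median thus depends on which genes are kept, and the difference between DESeq2 and edgeR cannot be assigned to the method alone. A test against a log2 fold change of 1 is stricter by construction and left 2581 genes for IMAT against VAT, 1079 for IMAT against SAT and 896 for VAT against SAT. At equal depth 1387 genes differed between VAT and SAT, as fewer counts were tested. Without VAT replicate 5 and SAT replicates 4 and 5, 4351 genes differed between IMAT and SAT and 226 were higher in SAT than in both others, with the dispersion within VAT and SAT lower. The genes higher in IMAT made up 69.6% of those differing from SAT, and over all alternatives from 54.9% (without those 3 libraries) to 93.4% (against a log2 fold change of 1). It was 59.1% without a filter, 75.2% with limma-voom and 63.6 to 79.5% with each library left out in turn. Leaving out each library in turn gave 4726 to 6120 genes for IMAT against VAT, 1962 to 3515 for IMAT against SAT, 1589 to 2432 for VAT against SAT and 4711 to 5816 in the joint test. The counts higher than in both other depots ran from 343 to 482 for VAT, from 38 to 144 for SAT and from 1308 to 1765 for IMAT. The share of IMAT counts in the genes higher in IMAT was 26.5% ± 12.6 (SD, n = 5) without ENSOMYG00000055678.

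Libraries of equal replicate number resembled each other only in part, and the main fit did not use the numbers. The deviations of the 15 pairs of equal number correlated at 0.116 on average (-0.132 to 0.532), with 9 above 0.1, against -0.0263 for the other 60 pairs, and 10 of 30 best matches fell on the library's own number. A mean as high was reached by a share of 0.0187 of 14400 rearrangements of the numbers, and by a share of 0.196 of 576 rearrangements when number 5 was left out, a check added after the data had been seen. With the replicate number as a block, 5879, 2819 and 2460 genes differed for IMAT against VAT, IMAT against SAT and VAT against SAT.

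Of 402 refits of single genes, 400 kept their direction and side of the threshold and 0 turned. For ENSOMYG00000055678 in IMAT against SAT, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave a log2 fold change of 2.00 and adjusted p = 0.0608 with the block, and adjusted p = 0.0569 against a log2 fold change of 1. The fits of 2 depots and the test against a log2 fold change of 1 give no joint test, and the latter no counts above both other depots. The planned tests of gene lists and the fits without marker genes of other cell types were not run. Depth limits the lowest transcripts in IMAT most, where 3 counts make up 0.714 to 1.24 CPM.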

Other observations

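The spread values that leave out libraries were chosen after the data had been seen. The biological coefficient of variation between libraries, which is the spread beyond counting noise, was 43.1% in VAT, 37.1% in SAT and 49.3% in IMAT. It was 27.7% in VAT without replicate 5, 22.2% in SAT without replicates 4 and 5 and 39.8% in IMAT without replicate 2.

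Divisions of the libraries other than the real depots gave fewer differing genes. In each case the real division was the only 1 of 100 divisions drawn that reached the real count, the smallest share that 100 divisions can give. The other divisions mix depots, which raises the spread within their groups and lowers their counts. The real counts were 5442 for IMAT against VAT, 2716 for IMAT against SAT and 2090 for VAT against SAT, and the highest of the other divisions gave 691, 0 and 14. Among divisions of all 15 libraries into 3 groups the joint test gave 5278 genes for the real depots and at most 646 for the others. The real counts of genes above both other groups were 412 in VAT, 96 in SAT and 1568 in IMAT, and the highest of any group in the other divisions was 18.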
